A study of Homo sapiens with 6 samples.

How the data were processed

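The series holds 6 ChIP-seq libraries from D283, an established Group 3 medulloblastoma cell line grown as tumorspheres, that is, as floating clusters under stem-cell culture conditions. OTX2 was silenced with 30 nM siRNA (OTX2low) or the cells received a scramble siRNA that targets no gene (OTX2high), per the labels' protocols. H3K4me3, a histone mark of active and poised promoters, and H3K27me3, the mark laid down by Polycomb repressive complexes, were each profiled in 1 library per condition. The other 2 libraries are IgG controls. Their titles and their silencing labels name opposite conditions, so they were assigned to no group, and no peak list of theirs was analysed here.

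Reads were aligned with Bowtie2 2.3.3.1 to GRCh38 and peaks were called with MACS2 2.1.1.20160309, per the submitters' processing notes. Per the file headers, each peak list was called on its own library against 1 IgG library at a q-value threshold of 0.05, as narrow peaks and without pooling. Each peak in the authors' lists has a pileup signal at its summit, a -log10 p-value, a -log10 q-value and a fold enrichment (a ratio of ChIP over local background). These are the peak's own values and served only to describe and filter peaks within a list. Per the file headers, MACS estimated fragment lengths of 189 and 181 bp for the H3K4me3 lists of OTX2high and OTX2low, and of 169 and 78 bp for the H3K27me3 lists labelled OTX2high and OTX2low. Peak widths depend on this estimate.

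The header of the H3K27me3 list labelled OTX2high names OTX2low as its library and its control, and the header of the list labelled OTX2low names OTX2high. These lists are therefore called by their sample label throughout, and no direction between conditions was taken from them alone. H3K27me3 directions below follow the condition names in the authors' differential table. Its read depths go with the header names, so these directions would be reversed if the sample labels were right.

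The authors' differential tables were made with diffReps 1.55.6, per the file headers, with a G-test of 1 library against 1, OTX2high as treatment and OTX2low as control. H3K4me3 was scanned with windows of 1000 bp in steps of 100 bp, and H3K27me3 with windows of 10000 bp in steps of 1000 bp, per the file headers. The authors' deposited columns hold read signal per region scaled by a normalization constant per library, a ratio of ChIP over IgG reads, a log2 ratio of OTX2high over OTX2low, a p-value and a Benjamini-Hochberg adjusted p-value. Their 4 columns of means per condition repeat the read columns at 1 library per condition and were not used here. A positive log2 value is thus higher in OTX2high. The authors' hotspot tables give clusters of such regions with the count of regions in each, an enrichment ratio and an adjusted p-value. A p of this kind compares the reads of 2 libraries, not the conditions, because no condition has a replicate. An adjusted p listed as 0 is printed as the authors' table gives it.

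For H3K4me3 a single read was worth 0.7977 in OTX2high and 1.2536 in OTX2low. Dividing by these steps gave whole reads within 0.05 for 98.1% and 99.9% of values. The G-test was recomputed on these reads with Benjamini-Hochberg adjustment over the 663990 windows given in the file header, and called 21714 of 21714 regions. These regions were already the authors' calls by that test, so this checks only the recovered read numbers. For H3K27me3 the same division gave whole numbers for 90.0% and 94.0% of values, so its read numbers are approximate. Intervals of 95% for a log2 ratio are exact conditional (Clopper-Pearson) intervals from these reads. They cover counting error only, since 1 library per condition holds no spread between libraries. Reads made by PCR are not independent molecules, so even the counting error may be understated.

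Genes were the 19974 protein-coding genes of chromosomes 1 to 22 and X in the GRCh38.p14 RefSeq gene table. The table used here gives gene starts and ends without strand, so the planned windows around transcription start sites were replaced by windows of 2000 bp around both ends of each gene. A peak or region touching such a window by at least 1 bp is said to lie at a gene end. A gene was counted as higher in a condition when all of its differential regions at gene ends had that direction, and as mixed when they had both. Its log2 value is that of its region with the most reads. Peaks were compared with bedtools 2.31.1, with a minimum overlap of 1 bp. Shares have Wilson intervals for peaks and exact Clopper-Pearson intervals for genes.

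Fixed before the data were examined were 15 gene lists with 567 distinct genes: PAX genes, photoreceptor genes of Group 3 tumors, neuronal differentiation, neural progenitors, HOX clusters, other developmental transcription factors, Polycomb and Trithorax, axon guidance, Wnt, Shh and BMP signaling, mTOR pathway, cell cycle and MYC, housekeeping, and markers of glia, of immune, blood and endothelial cells, and of mesenchymal, muscle and epithelial cells. Each list's value was ranked among 10000 random lists of the same size. Random lists were matched on H3K4me3 peaks for H3K27me3 shares and for H3K4me3 calls. For H3K27me3 calls they were matched on peaks of both marks, and for median log2 values on read number. For H3K4me3 shares they were unmatched. These percentiles describe the libraries and are not p-values. Named genes were OTX2, PAX3 and PAX6; per mark the 10 genes with the largest log2 value in each direction among regions at gene ends with adjusted p under 0.001 and at least 20 normalized reads; and up to 4 members of each list per mark and direction with the smallest adjusted p. Some genes that the rule selects are not reported here by name. Genes named outside this rule are said to be so, apart from neighboring genes and genes in hotspots, which are given for location.

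The G-test, the intervals and the percentiles were tested on simulated data. Reads for the 21714 H3K4me3 regions were drawn with 100 regions changed 2-fold and 100 changed 4-fold. The test recovered 50 of the 2-fold changes, all of them among the 62 with a mean of at least 20 reads, and 73 of the 4-fold changes, including 66 of the 66 with at least 20. It called 5 unchanged regions. The simulation adjusted over the 21714 regions and not over the 663990 windows of the data. Its means came from regions already called, and its Poisson reads hold no spread between libraries. Recovery by the test on the data themselves was therefore not measured. The interval held the true value in 968 of 1000 regions. Of 200 random lists, 12 (6%) stood beyond the 5th or 95th percentile, fewer than the 10% of an exact ranking. Alternatives were stricter peaks (-log10 q of at least 5, or fold of at least 4), equal numbers of peaks, other overlaps, windows of 1000 and 5000 bp, stricter differential regions, leaving out families of repeated genes (FAM90A, USP17L, DUX4, PRAMEF, NBPF, GOLGA) and genes with only a LOC number, and recentred log2 values. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.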

Results

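H3K4me3 and H3K27me3 were mapped in D283 tumorspheres with normal OTX2 (OTX2high) and after OTX2 silencing (OTX2low), to ask how the marks at transcription factor and other genes differed between these states. OTX2 is a homeodomain transcription factor highly expressed in Group 3 medulloblastoma. There was 1 library per mark and condition, so no difference below has a replicate check. After filtering, the H3K4me3 libraries held 33137731 (OTX2high) and 20914582 (OTX2low) tags. The H3K27me3 libraries held 40271458 tags (labelled OTX2high) and 33885628 (labelled OTX2low). The IgG libraries named in the headers held 85840108 (OTX2high) and 55079542 (OTX2low) tags.

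H3K4me3 marked nearly the same genes in both conditions. A peak lay at the ends of 13960 genes in OTX2high and 13796 in OTX2low, and 13665 genes had one in both. Another 295 genes had an H3K4me3 peak in OTX2high alone and 131 in OTX2low alone. The lists held 33201 peaks over 49.3 Mb in OTX2high and 28824 peaks over 40 Mb in OTX2low. Of the OTX2high peaks, 67.1% (95% Wilson interval 66.6 to 67.6%) were overlapped by an OTX2low peak, and of the OTX2low peaks 87.4% (87.0 to 87.8%) by an OTX2high peak. The deeper OTX2high library had the longer list.

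At OTX2 itself, the silenced gene, H3K4me3 was higher in OTX2high. In the authors' deposited table the region at chromosome 14, 56807601 to 56820000 (GRCh38), at the higher-coordinate end of the gene, had 3119 normalized reads in OTX2high and 1768 in OTX2low, a log2 ratio of 0.82 (95% counting interval 0.73 to 0.91), or 0.30 above the median over genes. The region at its other end had a log2 ratio of 0.68 in the authors' deposited table. No H3K27me3 peak lay at OTX2 in either list. Silencing by siRNA acts on the transcript, so these marks are no direct test of the knockdown. PAX3, a developmental transcription factor named in the study's title, had no H3K4me3 peak at its ends in either list. In the authors' deposited table its H3K27me3 region at chromosome 2, 222298001 to 222318000, was higher in OTX2low, with 1344 against 1064 normalized reads and a log2 ratio of -0.34 (-0.46 to -0.22). PAX6 carried both marks. According to the authors' deposited table its H3K4me3 was higher in OTX2high, at a log2 ratio of 0.63 (0.28 to 1.00), and its H3K27me3 higher in OTX2low, at -0.36 (-0.47 to -0.26). For PAX3 and PAX6 these ratios lay within 0.11 of the median over genes of the same mark, which was 0.52 for H3K4me3 and -0.34 for H3K27me3.

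H3K4me3 was higher in OTX2high at some photoreceptor genes, such as CRX, and higher in OTX2low at some neuronal differentiation genes, such as NHLH1. NHLH1, a basic helix-loop-helix factor of newborn neurons, had 98.1 normalized reads in OTX2high and 2154 in OTX2low in the authors' deposited table, 22-fold higher in OTX2low (log2 ratio -4.46, interval -4.73 to -4.19). Its region, at chromosome 1, 160364801 to 160373100, covered the whole gene. CRX, the homeodomain regulator of photoreceptor genes, had 1718 normalized reads in OTX2high and 379.8 in OTX2low in the authors' deposited table, 4.53-fold higher in OTX2high (2.18, interval 2.00 to 2.36). The CRX region, at chromosome 19, 47818701 to 47829400, also lay at an end of the neighboring gene TPRX1. The adjusted p was listed as 0 for both genes.

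Among the 38 neuronal differentiation genes, 12 had H3K4me3 higher in OTX2low, 7 higher in OTX2high, 2 mixed and 17 no differential region. Random lists, which were not matched on H3K27me3 peaks, had a median of 1 gene higher in OTX2low and 17 higher in OTX2high. The neuronal list stood at the 100th and the 0.01st percentile. Its median log2 ratio was -0.84 over 20 genes, below each of the 10000 random medians, and 15 of the 20 lay below the median over genes. BARHL1, a cerebellar granule neuron factor, was 4.89-fold higher in OTX2low in the authors' deposited table (log2 ratio -2.29, interval -2.65 to -1.94) in its region with the most reads, and is one of the 2 mixed genes. That table, the authors' deposited table, gave 4.03-fold for DCX, a microtubule protein of migrating neurons (-2.01, -2.29 to -1.74), and 2.77-fold for ELAVL3, a neuronal RNA-binding protein (-1.47, -1.63 to -1.31). The proneural factors NEUROD1 and NEUROG1 and the progenitor factor EOMES went the other way. Their log2 ratios were 0.70, 0.67 and 0.91 in the authors' deposited table, or 0.18, 0.15 and 0.39 above the median over genes.

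Among the 26 photoreceptor genes, 11 had H3K4me3 higher in OTX2high, none higher in OTX2low and 15 no differential region. Random lists had a median of 8 genes higher in OTX2high, and the count stood at the 90.7th percentile. The median log2 ratio was 0.87, at the 99.8th percentile of random lists, and 10 of the 11 genes lay above the median over genes. The number with an H3K4me3 peak was 15 in OTX2high and 11 in OTX2low, and no gene had one in OTX2low alone. IMPG2, a proteoglycan of the photoreceptor matrix, was 2.71-fold higher in OTX2high in the authors' deposited table (log2 ratio 1.44, interval 1.29 to 1.59). The list includes OTX2 itself.

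Among the 51 axon guidance genes, 12 had H3K4me3 higher in OTX2low, 15 higher in OTX2high and 3 mixed. Counts for this and the other lists take any called region, also one outside peaks or with few reads. They were not repeated with regions in peaks only. The number higher in OTX2low stood at the 100th percentile, and the median log2 ratio of -0.05 was below each random median. The authors' deposited table listed SLIT1 at -1.66, NRP2 at -1.62, EPHA3 at -1.36 and EPHB2 at -1.25, all guidance ligands or receptors and higher in OTX2low, while EPHA2 at 1.25 and EPHB1 at 1.00 were higher in OTX2high. Developmental transcription factors outside the PAX and HOX families showed both directions, with 39 genes higher in OTX2high, where random lists had a median of 63 (0th percentile), and 10 higher in OTX2low, where they had 6 (94.5th). Their median log2 ratio of 0.51 lay at -0.01 relative to the median over genes. Random lists for the H3K4me3 counts here were not matched on H3K27me3 peaks, which many developmental genes carry. Of 2284 genes with H3K4me3 peaks in both lists and an H3K27me3 peak, 538 were higher in OTX2high and 282 in OTX2low. Of all 13665 genes with H3K4me3 peaks in both lists, 7621 and 635 were. The percentiles of these counts therefore partly reflect H3K27me3. OLIG2, ONECUT1, EMX1 and DLX3 had log2 ratios of -1.50, -1.45, -1.14 and -1.10 in the authors' deposited table, and LHX8 had 0.86. Of the 58 Wnt, Shh and BMP genes, 19 were higher in OTX2high and 4 in OTX2low. BMP7 and FZD7 were at 1.32 and 1.18 in the authors' deposited table, and WNT7B and the Shh target GLI1 at -1.27 and -1.09.

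**Figure D1:**
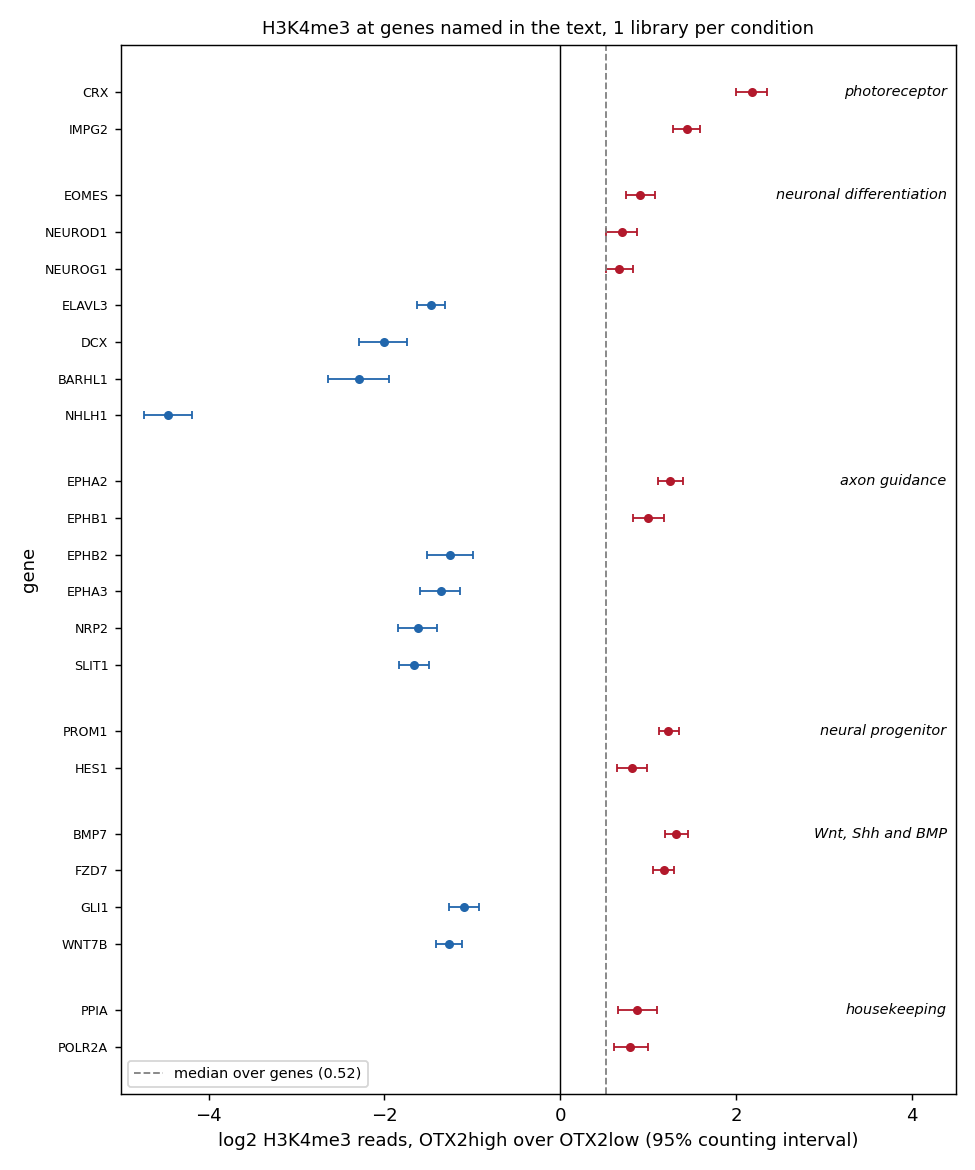
Log2 ratio of normalized H3K4me3 reads in OTX2high over OTX2low (x axis) for genes named in the text (y axis) of 6 lists, with 95% counting intervals from 1 library per condition, red where higher in OTX2high and blue where higher in OTX2low. NHLH1 lies at -4.46 and CRX at 2.18, and the dashed line marks the median over genes with a called region, 0.52.

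Most housekeeping and cell cycle genes, and few HOX genes, had H3K4me3 called higher in OTX2high. Random lists for these counts were not matched on read number, on which a call depends, or on H3K27me3 peaks. Of the 28 housekeeping genes, 26 were higher in OTX2high against a random median of 15 (100th percentile), none were higher in OTX2low and 1 was mixed. Their median log2 ratio was 0.55, at the 84.8th percentile of lists matched on read number and close to the 0.52 over all genes with a region. PPIA and POLR2A had 0.88 and 0.80 in the authors' deposited table. Of the 30 cell cycle and MYC genes, 25 were higher in OTX2high against a random median of 16 (99.97th percentile), with a median log2 ratio of 0.60 at the 99th percentile. AURKB and MCM2 were at 0.92 and 0.89 in the authors' deposited table, but the inhibitor CDKN1C at -1.15 and MYCN at -0.69. Inhibitors showed both directions in the authors' deposited table. CDKN1A was at 0.76, CDKN1B at 0.64 and CDKN2C at 0.51, and CDKN2B, in a region outside any peak, at -3.65. CDKN1B and CDKN2C are named outside the rule. The 24 neural progenitor genes had 12 higher in OTX2high, equal to the random median, and 1 higher in OTX2low, with a median of 0.61. The authors' deposited table gave PROM1 at 1.23 and HES1 at 0.82. Of 41 Polycomb and Trithorax genes 24 were higher in OTX2high, including PHC2 at 0.94 and EED at 0.82 in the authors' deposited table, and none was higher in OTX2low alone. Of the 32 mTOR pathway genes 19 were higher in OTX2high and 2 in OTX2low, and a median of 0.49 lay at -0.03 relative to the median over genes, with IRS1 at 1.17 in the authors' deposited table. Of the 39 HOX genes 33 had no region, 5 were higher in OTX2high against a random median of 16 (0.02nd percentile, with the median log2 ratio of 0.72 at the 59.5th) and 1, HOXA13 at -1.66 in the authors' deposited table, higher in OTX2low. Of the 9 PAX genes only PAX6 had an H3K4me3 difference.

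Among markers of other cell types, the glial and mesenchymal lists had about as many H3K4me3 differences as random lists. H3K4me3 peaks lay at 4 of the 20 immune, blood and endothelial markers in OTX2high and at 5 in OTX2low, and none had a differential H3K4me3 region, against a random median of 3 higher in OTX2high. Of the 19 mesenchymal, muscle and epithelial markers 6 had a peak in each condition and 3 were higher in OTX2high (random median 3). Of the 14 glial markers 4 were higher in OTX2high (random median 4) and 1 in OTX2low (random median 0). PDGFRA, a receptor of oligodendrocyte precursors, was at -1.13 in the authors' deposited table.

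The authors' deposited table for H3K4me3 listed 16038 regions higher in OTX2high and 5676 higher in OTX2low, and recentring the log2 ratios on their median of 0.61 turned this split into 10721 and 10814 by construction. Of the regions higher in OTX2low, 44.6% had under 20 normalized reads and 28.4% overlapped an H3K4me3 peak, against 73.9% of those higher in OTX2high. The rule of largest ratios therefore mostly chose weak regions outside peaks. GTF2B had 24.7 normalized reads in OTX2high and 0 in OTX2low in the authors' deposited table, and PPP1R17 had 0 and 22.6. NHLH1 was the 1 gene among these with over 100 reads.

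H3K27me3 peaks were frequent at developmental regulators in both lists. Peaks lay at 33 of 39 HOX genes in the list labelled OTX2high and at 32 in the list labelled OTX2low, at 7 and 6 of 9 PAX genes, at 85 (60.3%) and 71 (50.4%) of the other developmental transcription factors, and at 37 and 26 of 58 Wnt, Shh and BMP genes. All 8 of these counts stood above the 99.9th percentile of random lists matched on H3K4me3. Neuronal differentiation genes had 16 and 12 of 38, and axon guidance genes 21 and 14 of 51. Photoreceptor genes had 6 and 3 of 26, neural progenitor genes 6 and 4 of 24, Polycomb and Trithorax genes 5 and 3 of 41, mTOR genes 4 and 3 of 32, and cell cycle and MYC genes 4 and 3 of 30. No housekeeping gene had an H3K27me3 peak, which with 28 genes allows a share of up to 12.3% (exact interval). Glial markers had 6 and 4 of 14, immune, blood and endothelial markers 7 and 3 of 20, and mesenchymal, muscle and epithelial markers 2 and 2 of 19.

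**Figure D2:**
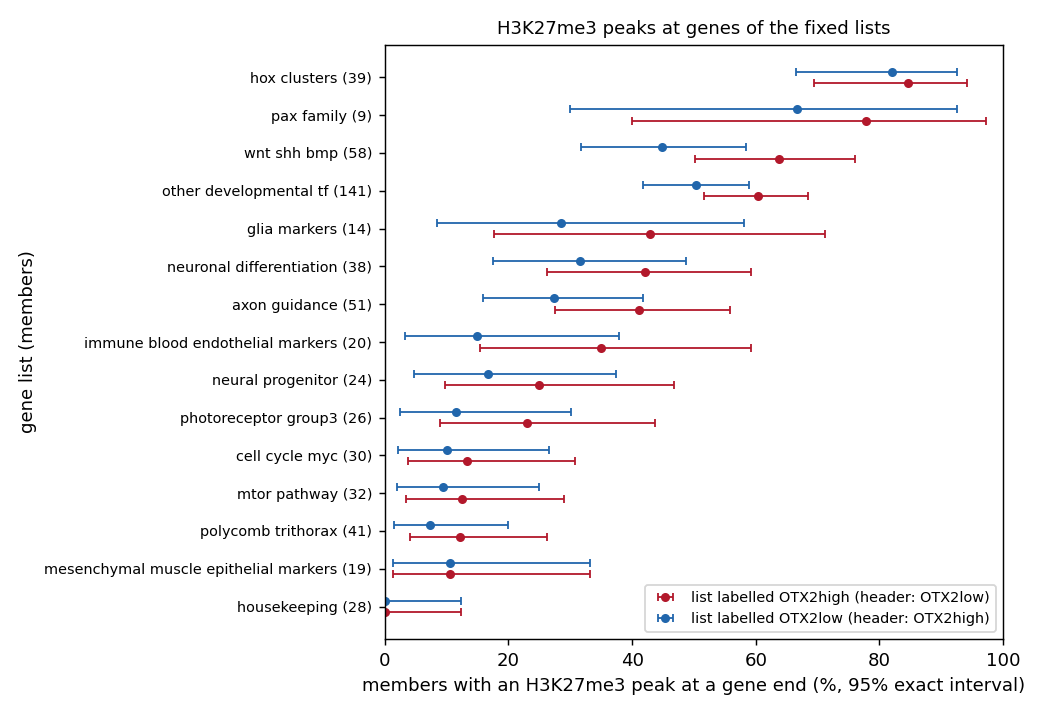
Percent of each list's genes with an H3K27me3 peak within 2000 bp of a gene end (x axis) for the 15 lists (y axis, with the number of genes), with 95% exact intervals, in the library labelled OTX2high (red) and the library labelled OTX2low (blue). HOX genes reached 84.6% and 82.1%, and housekeeping genes 0%.

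Across all genes, 4242 had an H3K27me3 peak in the list labelled OTX2high and 2755 in the list labelled OTX2low, with 2697 in both. The first list held 158878 peaks over 97.0 Mb and the second 102810 peaks over 20.2 Mb. Of the first list's peaks 25.9% (25.7 to 26.1%) were overlapped by the second, and of the second list's peaks 84.0% (83.8 to 84.3%) by the first. The file headers name the longer list OTX2low, opposite to its sample label, so these numbers show which library gave more peaks and not which condition did.

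By the condition names in the header of the differential table, H3K27me3 at gene ends was mostly higher in OTX2low. The read depths behind that table go with the peak-list headers and not with the sample labels. If the sample labels were right, every H3K27me3 direction given here would be reversed. Of 1628 genes with a region, 1294 were higher in OTX2low and 328 in OTX2high. Among HOX genes 22 were higher in OTX2low and none in OTX2high, and among the other developmental transcription factors 58 and 1. PAX genes had 6 and 0, and Wnt, Shh and BMP genes 19 and 0. Random lists for these counts were not matched on read number or enrichment, and strongly enriched regions of this mark were nearly all higher in OTX2low. Ranked among lists matched on read number, the median log2 ratio stood at the 54.7th percentile for the other developmental factors, the 27.6th for PAX genes and the 6th for Wnt, Shh and BMP genes. The ratios were small and mostly close to the -0.34 over genes with a called region. HOXD13 was at -0.36, PAX9 at -0.38, PAX7 at -0.34, PAX2 at -0.31 and the morphogen SHH at -0.49 in the authors' deposited table. The HOX median, -0.28, stood at the 99.99th percentile of lists matched on read number, nearer 0 than the -0.34 over genes. Neighboring HOX genes share regions, the 22 genes having 10 distinct ones, so random lists of scattered genes overstate how unusual the HOX counts and median are. NR2F1, a nuclear receptor of neural development, was at -0.77 (-0.95 to -0.59) in the authors' deposited table, SOX5 at -0.79 and SHISA9 at -0.82. These 3 regions were weakly enriched over IgG, with ratios in OTX2high and OTX2low of 1.44 and 2.48, 0.75 and 1.39, and 1.01 and 2.06. LHX4 was at -0.54, POU3F3 at -0.50, GATA6 at -0.45, BMP6 at -0.60, NEUROG2 at -0.52 and SOX2 at -0.36 in the authors' deposited table.

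In the other lists, 6 neuronal differentiation genes, 4 axon guidance genes, 4 neural progenitor genes, 3 photoreceptor genes and 2 genes each of the Polycomb and Trithorax, mTOR, cell cycle and MYC, glial and immune lists had H3K27me3 higher in OTX2low. Called higher in OTX2high were 2 axon guidance genes, EPHB2 and SEMA4A, and 1 mesenchymal, muscle and epithelial marker, MYOG. Their regions overlapped no H3K27me3 peak and were weakly enriched over IgG. The ratios in OTX2high and OTX2low were 1.63 and 0.93, 1.43 and 0.83, and 1.16 and 0.76. Under the naming rule, the largest ratio toward OTX2high at a gene end was that of MYO19 and ZNHIT3, which share a region. It was 1.09 (0.71 to 1.47) in the authors' deposited table. That region was not enriched over IgG, with ratios of 0.98 and 0.51.

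The direction of H3K27me3 regions followed their enrichment. The authors' deposited table held 3103 regions higher in OTX2high and 2298 higher in OTX2low. Of the regions enriched at least 4-fold over IgG, 1629 were higher in OTX2low and 18 in OTX2high, with a median log2 ratio of -0.35. Of those under 2-fold, 131 were higher in OTX2low and 2845 in OTX2high. H3K4me3 regions enriched at least 20-fold were higher in OTX2high in 7477 cases and in OTX2low in 479. Their median log2 ratio was 0.53, close to the 0.52 over genes with a called region. Log2 ratios of H3K27me3 were never below -1, and 5 regions exceeded 1.

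**Figure D3:**
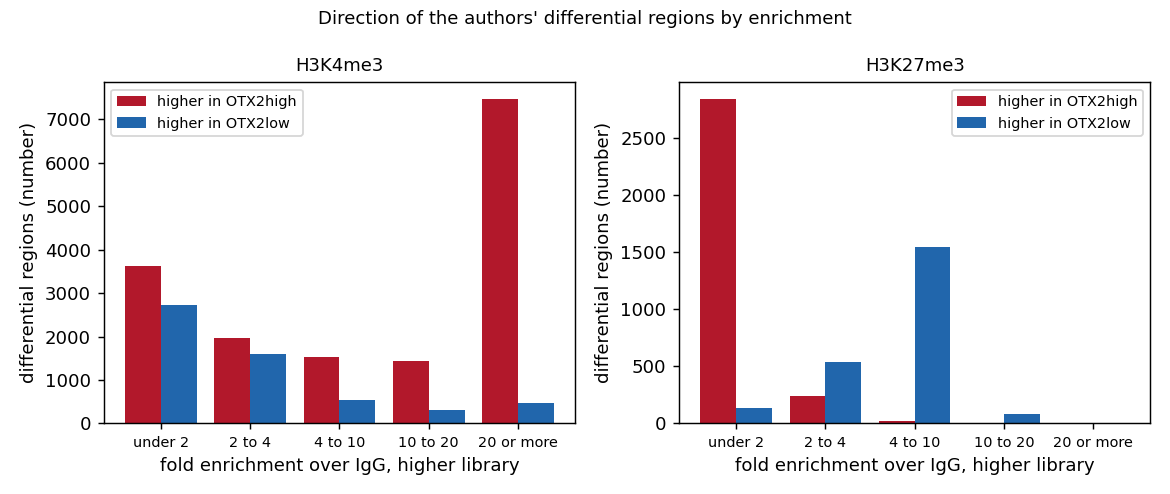
Number of the authors' differential regions (y axis) by fold enrichment over IgG in the library with more of it (x axis), for H3K4me3 (left) and H3K27me3 (right), red where higher in OTX2high and blue where higher in OTX2low. At 4-fold to 10-fold, 18 H3K27me3 regions were higher in OTX2high and 1547 in OTX2low.

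H3K27me3 regions higher in OTX2high were concentrated on chromosome 8, which held 651 of them, or 21.0%, on 5.05% of the autosome length, and 582 lay beyond 70 Mb. Chromosome 8 also had the highest IgG read density, 15.5 normalized reads per kb against a median of 8.25 over the 22 autosomes. Across the autosomes the number of such regions per 10 Mb and the IgG density had a Pearson's r of 0.78 (permutation p = 0.00072, adjusted 0.00432 over 6 relations) and a Spearman's rho of 0.25 (permutation p = 0.257, adjusted 0.514). Without chromosomes 8 and 7, the farthest from the median density, r was 0.37 (permutation p = 0.116, adjusted 0.347) and rho 0.0023 (permutation p = 0.994, adjusted 0.994), so the relation rests on those chromosomes. Regions higher in OTX2low showed no such relation that passed the test, with r = -0.07 (permutation p = 0.695, adjusted 0.857) and rho = -0.08 (permutation p = 0.714, adjusted 0.857).

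**Figure D4:**
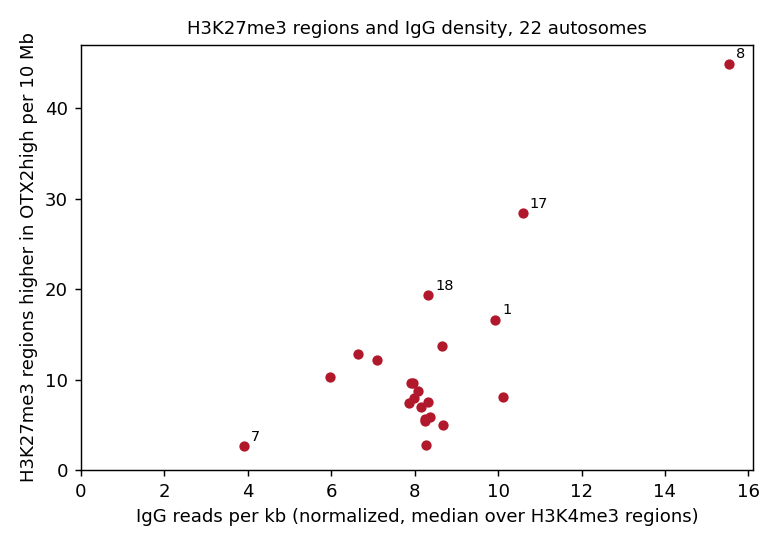
H3K27me3 regions higher in OTX2high per 10 Mb (y axis) against normalized reads per kb of the IgG library that the table's header names OTX2high (x axis), with 1 point for each of the 22 autosomes. Chromosome 8 lies at 44.9 regions per 10 Mb and 15.5 reads per kb, apart from the rest.

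Genes with both marks, often called bivalent, numbered 2323 in OTX2high and 1451 in OTX2low when the H3K27me3 lists were paired with H3K4me3 by sample label. Paired by the names in the file headers, the numbers were 1442 and 2325, which turns the direction. In each pairing the larger number went with the longer H3K27me3 list, which had a peak at 4242 genes against 2755. Genes with an H3K4me3 peak were nearly as many in OTX2low (13796) as in OTX2high (13960). The numbers therefore follow the length of the H3K27me3 lists and do not show a change in bivalent genes. Both marks in both conditions were found at 1351 genes. These have a peak in every list, so the pairing cannot change their number.

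Genes called higher in OTX2low for H3K4me3 and higher in OTX2high for H3K27me3 were more frequent than independent calls would give. Most H3K27me3 regions called higher in OTX2high were weak. Of all 3103, 2845 were enriched under 2-fold over IgG, and 1151 overlapped an H3K27me3 peak. For 33 genes H3K4me3 was called higher in OTX2low and H3K27me3 higher in OTX2high, against 12.9 for independent calls, a ratio of 2.56. The ratio fell to 1.69, from 17 genes, without families of repeated genes and genes without a name. Of the 33 genes, 14 had H3K4me3 peaks in both lists and an H3K27me3 peak, so the others do not show a change of 2 marks with peaks. DLX3, a homeodomain factor, was one of them, with -1.10 for H3K4me3 and 0.57 for H3K27me3 in the authors' deposited table, and EPHB2 another, with -1.25 and 0.85. The EPHB2 regions lie at opposite ends of the gene, and that of H3K27me3 was outside any peak, with ratios over IgG of 1.63 and 0.93. For 94 genes both marks were higher in OTX2low (ratio 1.85). H3K4me3 higher in OTX2high met H3K27me3 higher in OTX2low in 184 genes (ratio 0.36) and higher in OTX2high in 108 (ratio 0.84). Among the 2284 genes with H3K4me3 peaks in both lists and an H3K27me3 peak, the first ratio was 2.64, from 14 genes (2.35, from 9, without those families), but that for both marks higher in OTX2low turned to 0.82, from 72 genes. The other 2 ratios were 0.85 and 0.99. Genes are not independent replicates, and no test was made.

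Some clusters of differential H3K27me3 regions lay at developmental loci. The authors' deposited table of hotspots listed 61 for H3K27me3, of which 36 held only regions higher in OTX2low and 18 only regions higher in OTX2high, and 17 had an adjusted p under 0.05. Among those with the most regions, 5 were examined, and all their regions were higher in OTX2low. The first, with 11 regions on chromosome 22 (49353001 to 49738000, adjusted p = 0.0279 in the authors' deposited table), touched no end of a protein-coding gene. The others in the authors' deposited table had 8 regions around EN2 and SHH (chromosome 7, 155355001 to 155823000, adjusted p = 0.0214), 8 around PAX2 (chromosome 10, 100575001 to 100867000, adjusted p = 0.0459), 7 around GSX1, PDX1 and CDX2 (chromosome 13, 27786001 to 28052000, adjusted p = 0.00554), and 7 on chromosome 19 (3785001 to 3928000, adjusted p = 0.00554). No enrichment of developmental genes in hotspots was tested. For H3K4me3 the authors' deposited table listed 1964 hotspots, 1528 of them only with regions higher in OTX2high and 120 only with regions higher in OTX2low.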

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

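The tests of explanations in this part were chosen after the results were seen. Signal lay outside the comparisons above on sequences that belong to no assembled chromosome, where the 4 lists had 488 (H3K4me3 OTX2high), 584 (H3K4me3 OTX2low), 1468 (H3K27me3 labelled OTX2high) and 1955 (H3K27me3 labelled OTX2low) peaks. These peaks were drawn to attention because no gene comparison uses them. No explanation was tested for them.

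The names of the H3K27me3 lists conflict between sample label and file header. If the 2 lists were filed under each other's label, the library that the differential table calls OTX2low should match the list labelled OTX2high in depth. A single read counted 1.31 times as much in OTX2high as in OTX2low in the table, which makes OTX2low the deeper library, and the list labelled OTX2high had 1.19 times the tags of the other. For H3K4me3, whose labels and headers name the same conditions, the value of a read in OTX2high over OTX2low was 0.636 and the inverse ratio of tags 0.631. A mislabelled sample is therefore a candidate explanation. Peak coverage was not used for this, because the longer list covers more of any enriched region. This test compares depths and names inside the authors' files, so an error made before those files were named would stay unseen. If the sample labels were right instead, the H3K27me3 directions of the differential table would be reversed.

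H3K27me3 was higher in OTX2low where enrichment was strong and higher in OTX2high where it was weak. A difference in immunoprecipitation efficiency between the 2 libraries could give this, since it raises all enriched regions of a library together and lowers its background. The share of regions enriched at least 4-fold that were higher in OTX2low, 98.9%, is the pattern itself and decides nothing. A genome-wide rise of H3K27me3 after OTX2 silencing predicts this share and the median log2 ratio of -0.35 as well. The explanations cannot be told apart, because there is 1 library per condition and no spike-in was used here. The H3K4me3 median of 0.52 over genes with a called region, to which housekeeping genes were close, has the same limit. NHLH1, DCX and SLIT1 lie against it.

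H3K27me3 regions higher in OTX2high were concentrated on chromosome 8. A difference between the conditions specific to that chromosome stays open. The median log2 ratio of these regions was 0.57 there and 0.58 elsewhere, a difference of -0.01, but the threshold bounds both, so it decides nothing. More copies of chromosome 8 in this line are a candidate explanation, since more reads let the same weak ratio pass a threshold. IgG density there was 1.88 times the median autosome, against at most 1.28 times on any other. Density was measured at H3K4me3 regions and not over the whole chromosome.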

How the results depend on the processing

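Pairing by header, the gene span, the recomputed G-test, leaving out chromosome 8, leaving out families of repeated genes and recentring over genes were chosen after seeing the data. The recomputed G-test used only regions already called, so it could hardly change their number. No paired analysis was possible because each group has 1 library. The alternative with all transcript start sites was not run, since the gene table used has neither transcripts nor strand. Of the main values, 40 moved and 1 reversed, all given below. Another 93 main and 512 further values kept their direction and stayed within 1.5 times or their interval, and 36 counts, nearly all of a few genes in a list, moved by more. Under the other windows and at adjusted p under 0.001, genes with H3K4me3 higher in OTX2low numbered 11 to 13 in the neuronal and 10 to 13 in the axon guidance list, and 8 to 13 photoreceptor genes were higher in OTX2high. H3K27me3 was higher in OTX2low for 21 to 23 HOX genes and 57 to 60 other developmental transcription factors. Few reads limited recovery in the simulation, with 73 of 100 changes of 4-fold recovered, and 66 of 66 with at least 20 reads. Its adjustment was over fewer tests than in the data, so these shares do not carry over.

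With -log10 q of at least 5, the H3K27me3 lists labelled OTX2high and OTX2low kept 76327 and 20751 peaks. The first list fell to 74009 peaks with a fold of at least 4 and to 102810 with equal numbers. The share of overlapped H3K4me3 peaks in OTX2high was 75.8% with the stricter q, 75.1% with equal numbers, 75.6% with a fold of at least 4, 60.3% with 50% of the peak overlapped and 76.5% with merged peaks. For H3K4me3 in OTX2low these shares were 93.5%, 85.9%, 90.4%, 84.4% and 91.5%. For the H3K27me3 list labelled OTX2high they were 12.3%, 35.3%, 37.7%, 2.40% and 33.1%. For the list labelled OTX2low they were 79.3% with equal numbers, 77.9% with a fold of at least 4, 79.1% with 50% overlapped and 74.9% with merged peaks. The cause was not tested for these shares.

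With the stricter q, 1362 genes had an H3K27me3 peak in the list labelled OTX2low, and 74 had H3K4me3 in OTX2low alone. Paired by sample label, 721 genes had both marks in OTX2low at that q, and pairing by header was not run there. With all peaks, pairing by header gave 1442 and 2325 genes with both marks. The difference of OTX2low minus OTX2high thus turned from -872 to 883, by construction.

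At adjusted p under 0.001, 10202 H3K4me3 regions were higher in OTX2high and 2383 in OTX2low. An absolute log2 ratio of at least 1 left 7639 higher in OTX2high for H3K4me3, and 5 in OTX2high and 0 in OTX2low for H3K27me3. At least 20 reads left 3142 H3K4me3 regions higher in OTX2low, an overlapping peak left 1610 of them and 1151 H3K27me3 regions higher in OTX2high, and recentring gave 10814. Over gene spans with 5000 bp on either side, the ratio for H3K4me3 higher in OTX2high with H3K27me3 higher in OTX2low was 0.47, and that for both higher in OTX2low 2.33. Without families of repeated genes, the ratio for H3K4me3 higher in OTX2low with H3K27me3 higher in OTX2high was 1.69, from fewer genes. The cause was not tested. Recentred on the median over genes, 4 list medians changed sign: H3K27me3 of HOX genes to 0.065 and of axon guidance genes to 0.005, and H3K4me3 of other developmental transcription factors to -0.01 and of mTOR genes to -0.03.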

Other observations

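The rule of at least 100 reads within a peak, used in this paragraph, was chosen after seeing the data, and the genes are named after their values were seen. Under it the H3K4me3 regions with the largest ratios toward OTX2high in the authors' deposited table lay at CPLX4, a complexin of retinal ribbon synapses (9.06-fold, log2 ratio 3.18, interval 2.51 to 3.93), TRPM1, a cation channel of retinal bipolar cells (6.92-fold, 2.79, 2.41 to 3.19), HSD17B2 (6.02-fold) and AGBL1 (5.78-fold). Among smaller ratios, RD3, which controls guanylate cyclase in photoreceptors, was 5.13-fold higher and CACNA2D4, a calcium channel subunit of photoreceptors, 4.26-fold in the authors' deposited table. None of these 6 is in the photoreceptor list fixed beforehand, and no enrichment of retinal genes was tested. Toward OTX2low, NHLH1 was followed in the authors' deposited table by GLYCTK (9.78-fold), NYAP2 (8.75-fold), B3GALT2 (8.40-fold), IFITM10 (7.73-fold) and MFNG, a Notch-modifying glycosyltransferase (7.41-fold). Among smaller ratios the authors' deposited table gave 6.50-fold for NPTXR, a neuronal pentraxin receptor, 5.43-fold for the adhesion protein CNTN5, 5.31-fold for the sodium channel SCN3A and 5.10-fold for the neural adhesion protein L1CAM, and no enrichment of neuronal genes was tested.

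In the authors' deposited table the 14 genes with peaks of both marks, H3K4me3 higher in OTX2low and H3K27me3 higher in OTX2high include NPTXR (log2 ratios -2.70 and 0.45), SCRT2, a neuronal zinc finger repressor (-1.54 and 0.55), NFASC, a neuronal adhesion protein (-0.90 and 0.32), and BRINP1 (-0.81 and 0.74), with DLX3 and EPHB2 named above, all picked from the 14 after their values were seen. The 14 also include FAM90A12, FAM90A24 and DUX4, members of repeated gene families whose reads cannot be placed with certainty. Of the 18 H3K27me3 regions enriched at least 4-fold and higher in OTX2high, most lay in such families (USP17L, FAM90A, NBPF, PRAMEF, GOLGA). The NPTXR region, at chromosome 22, 38829001 to 38844000, in the authors' deposited table had 658.6 normalized reads in OTX2high and 481.0 in OTX2low.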
